A study of Mus musculus with 15 samples.

How the data were processed

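Bulk RNA sequencing was done on microglia sorted from mouse forebrain by intermediate CD45 and CD11b staining, after transient occlusion of the middle cerebral artery for 60 minutes or after sham surgery. The sorted cells were also stained for CD31. RNA was turned into libraries with an Ovation SoLo kit and sequenced on a HiSeq instrument, except the libraries of Igf1-Egfp mice on day 14, which were sequenced on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name STAR, featureCounts and edgeR and the genome builds mm10 and GRCm38, with no roles, versions or annotation given in the sources used here.

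The values came as 3 deposited tables with the same 24421 genes. The table of the wild-type time course with the day 6 EGFP libraries and the table of the day 14 EGFP libraries held whole read counts per gene, as deposited, with no normalization. The Yy1 table held fractional values, as deposited by the authors without normalization, and was taken here to hold expected counts, since between 3.55% and 4.75% of the values in each library were not whole. How those fractions arose was not stated in the sources used here. The expected counts were rounded to whole numbers before every test. Groups were taken from the sample titles, and 0 columns were left unused. In each table, date-like names were carried by 27 genes, which were kept in library sizes but never named, and mitochondrially encoded genes were not listed.

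The total count per library ran from 10.5 to 13.9 M (M, 1e6 counts) in the Yy1 table, from 16.8 to 52.6 M in the time course with the day 6 EGFP libraries, and from 23.1 to 24.6 M in the day 14 EGFP table. Counts from 1 to 20 were even in 68.7% to 90.9% of cases in the tables of whole counts and in 44.2% to 48.2% of cases in the Yy1 table. If the even counts arose by counting both mates of a fragment, counting intervals from the whole-count tables are too narrow, and no fold bound is given there for a gene at 0 counts. Intervals and floors cover counting error only, since reads were not tied to molecules. The floor used for a group at 0 in the Yy1 comparison was 3 counts over the group.

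For the Yy1 comparison, 3 floxed control libraries and 3 Yy1-deleted libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr, were scaled by TMM and were tested with edgeR's two-sided quasi-likelihood F-test without a block for the replicate number. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. These p-values measure the spread between these 6 samples. Standard errors were taken from the fold change and its F statistic. The groups share replicate numbers 1 to 3, and the labels do not say that a number marks a shared litter or day.

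Gene lists were tested in the Yy1 libraries with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 30 lists were fixed before the data were examined, as were the tests, the size rules and the rule for naming genes. Lists with at least 5 measured members were tested. A further 6 lists were derived from libraries outside the Yy1 table and adjusted among themselves.

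The wild-type time course had 1 library per time point, and each EGFP state had 1 library per day. These comparisons gave log2 ratios of TMM-scaled CPM plus a pseudocount of 1 CPM, which understates the change of low genes. Fold ratios had exact conditional binomial intervals (Clopper-Pearson, 95%). No p-value was computed for them. A gene passed the size rule at an absolute log2 ratio of 2 in the time course or 1 between EGFP states, with at least 20 CPM in one of both libraries. List medians used members with at least 5 CPM in 1 library of the table and were placed among 10000 random lists of the same size matched on mean expression in 20 bins. The 4 EGFP libraries were also fitted together with edgeR, with day and EGFP state as additive terms and 1 residual degree of freedom. The day 14 EGFP table was scaled apart from the other tables, and the day term holds table, sequencer and library preparation as well as time.

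Genes were named by rule. Yy1, Cx3cr1, Igf1, Spp1, Zfp384, P2ry12, Tmem119, Apoe, Lpl, Gpnmb, Il1b and Mki67 were always considered. The Yy1 comparison added the 10 highest and 10 lowest fold changes among called genes with groups that did not overlap and at least 10 CPM in 1 group. The time course added the 8 highest and 8 lowest ratios per comparison, and the EGFP comparisons added the 10 highest and 10 lowest mean ratios over both days. Up to 4 passing members of each fixed list were added everywhere. Genes outside the rule are said to have been chosen after their values were seen. The result of 1 gene picked by this rule is not reported here.

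The procedures were tested on simulated data made from the real means and library sizes. The simulated Yy1 comparison had 200 changed genes and a squared coefficient of variation of 0.1, against a common dispersion of 0.332 in the real libraries, so its shares describe less variable data. Over 12945 genes, edgeR recovered 16.0% of genes changed 2-fold and 100% of genes changed 8-fold, with 4.13% false calls, and camera called the 1 raised list and 0 others. In the EGFP fit, simulated with the same spread over 13642 genes, the shares were 8% and 99%, with 2.73% false calls. In a pair of day 6 and sham libraries simulated with counting noise alone over 24421 genes, 100% of genes changed 8-fold at 100 CPM or more passed the size rule, and 0 unchanged genes did.

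Alternatives covered scaling by RLE or by total counts, DESeq2 1.42.0 and limma-voom in place of edgeR, other expression filters, an estimated correlation in camera, the replicate number as a block, each replicate left out, another pseudocount and other CPM minimums. Gene positions came from GENCODE vM21 on GRCm38, in which 23350 of the 24421 symbols were found. Overlapping genes and genes with near-identical copies are uncertain, since the counting rules were not given in the sources used here.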

Results

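Gene expression was measured in microglia, the resident macrophages of the brain, sorted from mouse forebrain after an ischemic stroke. The wild-type time course held 1 library each from sham-operated mice and from days 1, 6, 14 and 28 after stroke. Igf1-Egfp reporter mice gave 1 EGFP-positive and 1 EGFP-negative library on day 6 and again on day 14. On day 6, 3 libraries of Yy1flox/flox mice, called floxed controls here, were set against 3 libraries of Cx3cr1-CreER;Yy1flox/flox mice, called Yy1-deleted here. The controls carried no Cre, so effects of Cre and of the deletion are not separated. Total counts, in M (1e6 counts), were 52.6 in sham, 46.4 on day 1, 42.5 on day 6, 16.8 on day 14 and 22.7 on day 28. They were 44.1 in EGFP-negative and 29.6 in EGFP-positive cells on day 6, and 24.6 and 23.1 on day 14. Replicates 1 to 3 held 11.6, 11.0 and 13.9 in floxed controls and 10.5, 12.8 and 10.6 in Yy1-deleted libraries.

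The time course asks which genes differ in the sorted cells at each stage after stroke. On day 1, 13 of 28 genes of disease-associated microglia were past the size rule above sham, and 13 of 23 genes of homeostatic microglia were past it below. Spp1, which encodes the secreted matrix protein osteopontin (GRCm38 chromosome 5, 104435118 to 104441050), stood at 7.12 CPM in sham and 5915 CPM on day 1. Among the highest ratios were the protease genes Adam8 (log2 ratio 8.06) and Mmp12 (7.97), the interleukin-1 antagonist gene Il1rn (7.90) and the scavenger receptor gene Msr1 (7.90). The chemokine gene Cxcl2 (6.62), the galectin gene Lgals3 (6.70) and the lipid droplet coat gene Plin2 (4.60) were higher as well. P2ry12, a purinergic receptor gene of resting microglia, stood at 6022 CPM in sham and 401 CPM on day 1. The fructose transporter gene Slc2a5 (log2 ratio -4.10), Gpr34 (-3.41), Tmem119 (-2.75) and Sall1, a transcription factor of microglial identity (-2.50), were lower too. Inflammatory cytokines and chemokines as a list had a median log2 ratio of 1.71, with Il1b at 83.7 CPM against 4.78 CPM, and the genes of glycolysis and hypoxia had a median of 1.14, with Pkm at 2.66.

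By the size rule 403 genes were higher and 144 lower on day 1 than in sham, of 7203 genes considered. The 23 homeostatic microglia genes had a median log2 ratio of -2.29, at percentile 0 among random lists, and the 28 disease-associated microglia genes had a median of 2.04, at percentile 100. None of the time-course comparisons has replicates, so no ratio in them could be set against a spread between mice. Markers of neutrophils (median log2 ratio 4.55) and monocytes (2.91) were also higher on day 1, with S100a8 at 490.3 CPM. Here and on the later days, bulk values do not separate a change within microglia from a change in the cells present.

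On day 6 Igf1, Spp1, Apoe and Mki67 stood far above sham, with 5 of 24 genes of lipid uptake and efflux, 2 of 19 growth factor genes and 9 of 31 cell cycle genes past the size rule. Igf1, the growth factor gene of the reporter mice (chromosome 10, 87858265 to 87937042), stood at 2.36 CPM in sham, 41.2 CPM on day 1 and 231 CPM on day 6. The day 6 to sham fold ratio of Igf1 was 97.7 (counting interval 81.9 to 117). Gpnmb, a membrane glycoprotein gene of lipid-laden macrophages, had the highest log2 ratio of the named genes at 7.20, followed by Spp1 at 6.52. Apoe, which encodes a lipid carrier, stood at 6183 CPM against 130.3 CPM, and the fatty acid binding gene Fabp5 (4.75), Cd5l (5.04) and the phagocytic receptor gene Axl (4.17) were higher too. The proliferation gene Mki67 stood at 296 CPM against 18.7 CPM, and Top2a had a log2 ratio of 4.03. The interferon-stimulated gene Oasl2 had a log2 ratio of 3.73. P2ry12 stood at 1839 CPM, between its day 1 and sham levels.

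By the size rule 443 genes were higher and 6 lower on day 6 than in sham, of 7092 considered. The lower genes were Gpr165, Tlr5, Trp53cor1, Sema4b, Cass4 and Bank1, with log2 ratios from -3.42 to -2.17. List medians on day 6 were 2.35 for disease-associated microglia, 2.66 for interferon response, 2.45 for cell cycle and -1.06 for homeostatic microglia. Against day 1, 163 genes were higher and 116 lower on day 6, with medians of 1.21 for homeostatic microglia, 1.83 for cell cycle and -0.97 for cytokines and chemokines. The endothelial and mural markers had a median of 3.34 over sham on day 6, with Vwf at 1475 CPM. Markers of neutrophils (median 2.18, 5 of 11 past the size rule) and monocytes (0.81, 3 of 12, with Fn1 at 1361 CPM) were higher as well.

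On day 14 Spp1, Igf1, Gpnmb and Apoe stood far above sham, while the lipid uptake and efflux list (median log2 ratio 0.00, percentile 79.9) and the growth factor list (0.20, percentile 87.0) lay within the range of random lists. Spp1 stood at 1349.6 CPM, Igf1 at 176 CPM, Gpnmb at 70.8 CPM and Apoe at 3862 CPM. Cst7, which encodes an inhibitor of lysosomal proteases, had a log2 ratio of 6.06 over sham, and the interferon-induced gene Ifitm3 a ratio of 4.68. The growth factor genes Tgfb2 (3.63) and Tgfb3 (3.67) were higher as well. The transcription factor gene Maf (-2.52) and the receptor genes P2ry13 (-2.35), P2ry12 (-2.31) and Gpr34 (-2.18) were lower. The vascular genes Sele (6.72), Cldn5 (5.05) and Tek (4.87) and the collagen gene Col1a1 (6.06) stood among the higher genes.

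By the size rule 1008 genes were higher and 534 lower on day 14 than in sham, of 7833 considered. Medians were 2.74 for disease-associated microglia, 2.92 for interferon response, 0.89 for cell cycle, -1.55 for homeostatic microglia and 4.49 for endothelial and mural markers. They were 2.58 for oligodendrocyte lineage markers (3 of 7 past the size rule higher and 1 lower) and 1.06 for dissociation and immediate early genes (4 of 21 higher and 0 lower). Of the 6307 genes with at least 20 CPM in sham, 39 (0.618%) had 0 counts on day 14 and 194 (3.08%) on day 28, against 0 on days 1 and 6, so part of the lower genes on those days had few counts. Patz1 was among them, at 43.4 CPM in sham and 0 counts on day 14. Over all genes, 16009 had a count in sham, 17321 on day 1, 17007 on day 6, 11823 on day 14 and 9886 on day 28. Ratios of single genes on days 14 and 28 are therefore less certain in both directions. Scaling by RLE in place of TMM shifted the log2 ratios against sham by 0.17 on day 14 and 0.12 on day 28, and scaling by total counts shifted them by 0.11 on day 14.

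Day 28 combined high antigen presentation and cytokine genes with Igf1, Spp1 and Gpnmb levels well under those of day 6. Markers of monocytes, dendritic cells and neutrophils were higher than in sham as well. These levels therefore do not tell a change within microglia from a change in the cells present. The MHC class II genes H2-Aa (log2 ratio 7.42 over sham) and H2-Ab1 (6.98) and the invariant chain gene Cd74 (6.29) were among the highest, and H2-Aa stood at 1189 CPM against 5.96 CPM. Il1b stood at 232 CPM, its highest level in the time course. The dendritic cell genes Flt3 (6.22) and Cd209a (6.52) were also higher, and Ccr7, a homing receptor gene, stood at 162 CPM against 0 counts in sham. Igf1 stood at 29.5 CPM, Spp1 at 126 CPM and Gpnmb at 38.2 CPM, with log2 ratios to day 6 of -2.92, -2.55 and -2.20. Apoe, at 2513 CPM, had a log2 ratio of -1.30 to day 6 and 4.26 to sham. Tmem119 stood at 223 CPM against 1163 CPM in sham, and Cx3cr1, the fractalkine receptor gene, at 2437 CPM against 5027 CPM. Yy1 and Zfp384 stood at 174 CPM and 255 CPM on day 28 against 87.4 CPM and 129 CPM in sham.

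By the size rule 845 genes were higher and 1158 lower on day 28 than in sham, of 7616 considered. The balance depends on the minimum: at 50 CPM 465 were higher and 352 lower, and at 5 CPM 2970 were lower. With at least 10 counts in both libraries 628 were lower. Against day 6, 696 were higher and 1395 lower by the size rule. At 50 CPM they were 374 and 435, and at 5 CPM 3623 were lower. With at least 10 counts in both libraries 649 were lower. Medians over sham were 1.47 for antigen presentation, 1.83 for cytokines and chemokines, 1.30 for cytosolic ribosomal proteins and -1.03 for homeostatic microglia. Against day 6, the medians were -0.94 for disease-associated microglia, -0.78 for lysosome and 1.35 for antigen presentation. The cell cycle median against day 6 was -3.19, where random lists ran from -2.81 to -0.26, and it rests on near-empty genes: Cenpe, Cenpf and Stmn1 had 0 counts on day 28 while Mki67 had a log2 ratio of -0.45. Marker lists of monocytes (5.47), dendritic cells (3.49) and neutrophils (3.73) were higher than in sham, and endothelial and mural markers were lower (-3.76; -6.94 against day 6), with Vwf at 1.14 CPM.

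**Figure D1:**
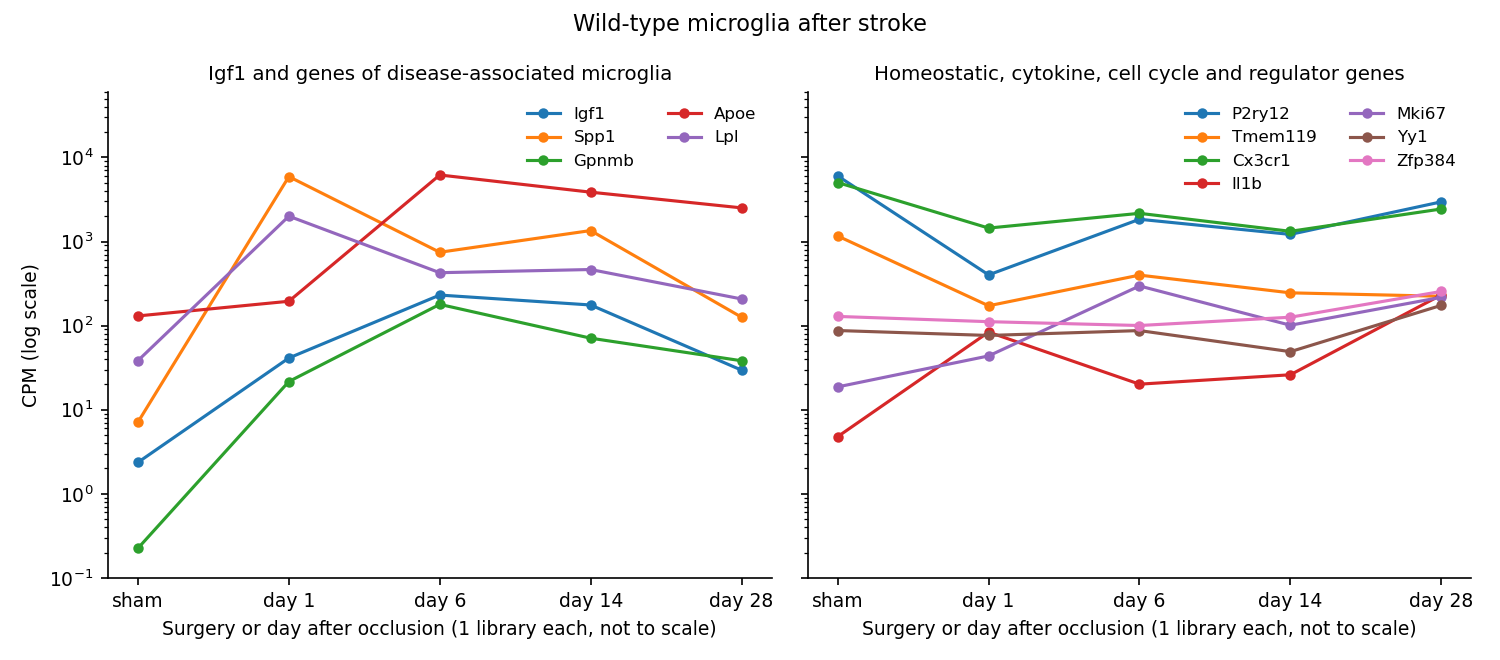
Normalized expression (CPM, log axis) of the always-named genes in the 5 wild-type libraries, from sham to day 28, with 1 library per point. Igf1 was highest on day 6 at 231 CPM, and P2ry12 was lowest on day 1 at 401 CPM.

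**Figure D2:**
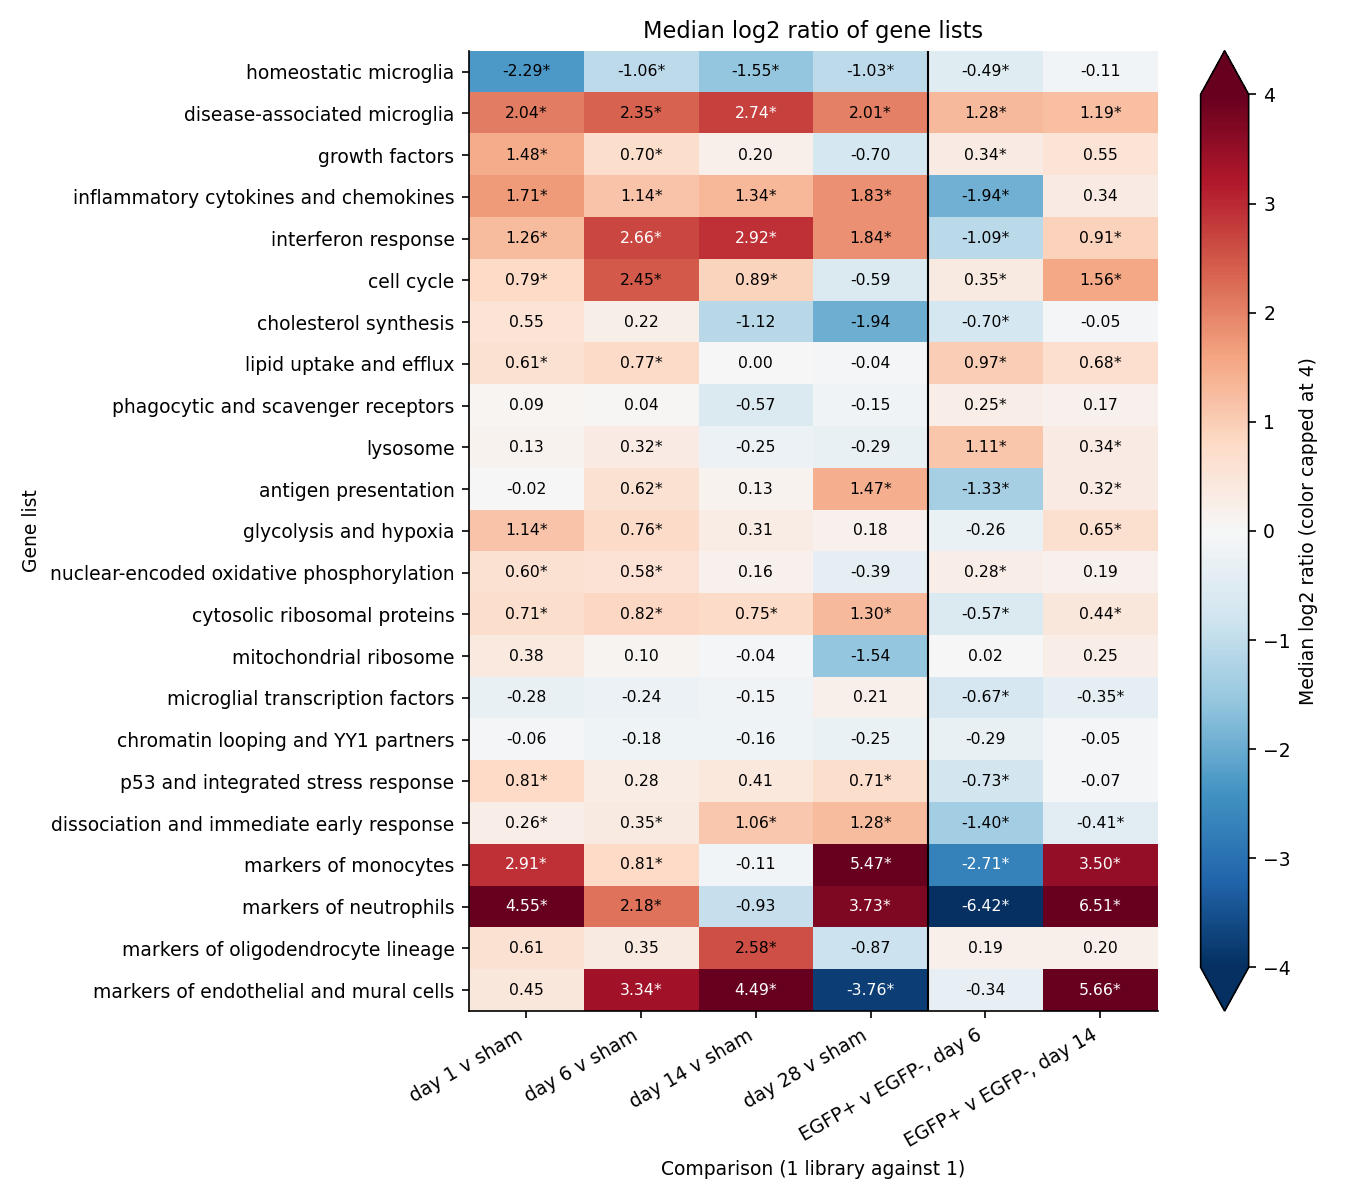
Median log2 ratio of each gene list (color, capped at 4) for the 4 time points against sham and for EGFP-positive against EGFP-negative cells on days 6 and 14, with an asterisk where the median lies at or beyond the central 95% of random lists. Homeostatic microglia had medians from -2.29 to -1.03 against sham.

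The reporter comparison asks what distinguishes microglia that express Igf1. On day 6, 17 of 28 genes of disease-associated microglia were past the size rule higher in EGFP-positive cells and 3 lower, and of 24 genes of lipid uptake and efflux 12 were higher and 0 lower. Igf1 itself stood at 813 CPM in EGFP-positive and 49.5 CPM in EGFP-negative cells on day 6, and at 33.5 CPM and 11.1 CPM on day 14. Gpnmb stood at 3913 CPM against 123 CPM on day 6 and 102 CPM against 27.6 CPM on day 14. The days were scaled in separate tables and differ in sequencer. CPM levels are therefore comparable between EGFP states within a day, and not between the days. Spp1 had log2 ratios of 4.25 on day 6 and 0.88 on day 14, Apoe 2.52 and 1.58, Fabp5 3.78 and 1.69, and the lipase gene Lpl 2.47 and 1.68. Msr1 (2.00 and 4.66) was higher in EGFP-positive cells on both days. On day 14 the phospholipid transfer gene Pltp stood at 104 CPM and the sialoadhesin gene Siglec1 at 41.6 CPM in EGFP-positive cells, and both had 0 counts in EGFP-negative cells. Their log2 ratios on day 6 were 1.81 and 1.93. On day 14 the EGFP-negative library had counts in 10892 genes and the EGFP-positive library in 12498. In the former, 0 counts therefore do not show that a gene was not expressed.

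Of the 21 dissociation and immediate early genes, 17 were past the size rule lower in EGFP-positive cells on day 6 and 0 higher, and 4 were lower and 1 higher on day 14. Ratios on day 6 and day 14 were -1.51 and -4.56 for the AP-1 gene Jund, -1.26 and -2.90 for Ier5, and -1.56 and -2.20 for the transcription factor gene Klf2. They were -1.40 and -2.58 for the mRNA decay gene Zfp36l2 and -2.78 and -1.05 for the heat shock gene Hspa1a. Il1b stood at 2.16 CPM in EGFP-positive and 438 CPM in EGFP-negative cells on day 6, and at 52.98 CPM and 40.1 CPM on day 14. The EGFP-negative day 6 library also held high levels of the neutrophil gene S100a8 (3106 CPM) and the monocyte genes Chil3 (1751 CPM) and Ccr2 (698 CPM), against 35.2, 228 and 64.5 CPM in EGFP-positive cells. Bulk values do not tell whether the day 6 differences in Il1b, Klf2 and the immediate early genes lie within microglia or in the cells present. P2ry12 (-0.93 and -0.44), Tmem119 (-0.18 and -0.63) and Cx3cr1 (0.26 and 0.07) did not pass the size rule on either day.

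By the size rule 546 genes were higher and 862 lower in EGFP-positive cells on day 6, and 795 and 772 on day 14. Of 5658 genes with at least 20 CPM on both days, 57 were higher on both (38.4 if the days were independent) and 51 lower on both (48.0). Another 77 were lower on day 6 and higher on day 14 (53.6 if independent), and 30 the other way (34.3). Across these genes, which are not independent replicates, the ratios of the days had a Pearson r of -0.0463 and a Spearman rho of 0.0772. Medians on day 6 and day 14 were 1.28 and 1.19 for disease-associated microglia, 0.97 and 0.68 for lipid uptake and efflux, 1.11 and 0.34 for lysosome, and -1.40 and -0.41 for the dissociation and immediate early genes. Scaling by total counts shifted the day 14 ratios by -0.10.

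With both days fitted together, edgeR called 0 of 12842 genes in either direction, with 193 at an unadjusted p under 0.05, limma-voom called 0 with 389, and DESeq2 called 18 higher and 13 lower. The Igf1 coefficient in edgeR was 2.83 (SE 0.79, adjusted p = 1). DESeq2 called Igf1 (adjusted p = 0.0216), Gpnmb (0.00538), Apoe (0.00387) and Lpl (0.00387) higher and Klf2 (0.00870) lower, and the adjusted p of Igf1 ran from 0.0216 to 1 over the alternatives. This fit has 1 residual degree of freedom, and its day term also holds the table and the sequencer. Genes higher in EGFP-positive cells on both days had a median log2 ratio in wild-type cells of 1.21 on day 6 and 0.10 on day 28 over sham, and of -1.61 on day 28 against day 6. They include genes picked in separately scaled tables.

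**Figure D3:**
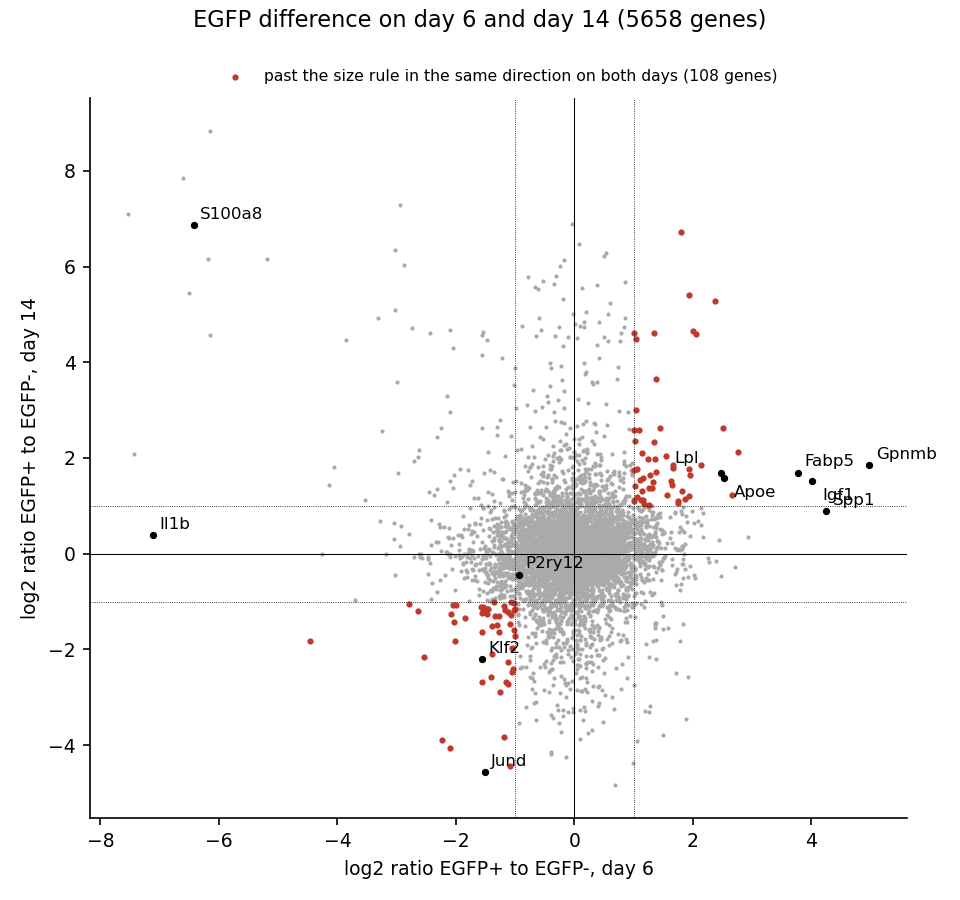
Log2 ratio of EGFP-positive to EGFP-negative cells on day 6 (x axis) and day 14 (y axis) for 5658 genes, 1 library per state and day, with the 57 genes higher and 51 lower on both days in red. Igf1, Gpnmb, Apoe and Lpl lie above 1 on both axes, and Jund lies at -1.51 and -4.56.

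The Yy1 comparison asks how deleting the transcription factor gene Yy1 from Cx3cr1-expressing cells changes microglia on day 6 after stroke. Yy1 (chromosome 12, 108792973 to 108820148) stood at 76.1, 50.9 and 57.9 CPM in floxed controls and 32.5, 28.9 and 38.8 CPM in Yy1-deleted libraries. The means were 61.6 ± 13.01 and 33.4 ± 4.99 CPM (SD, n = 3), and the log2 fold change was -0.88 (SE 0.28, edgeR adjusted p = 0.128), with adjusted p from 0.0694 to 0.569 over 13 alternatives, none of which called it. All 3 Yy1-deleted libraries lay below all 3 controls. A gene count does not show whether the deleted exon was read, so the reduction measured here need not equal the share of cells that lost the gene. Zfp384, which encodes a zinc finger factor, did not change detectably (97.3 and 86.7 CPM, log2 fold change -0.17, SE 0.20, adjusted p = 0.811), and neither did Mki67 (0.16, SE 0.19, adjusted p = 0.823).

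Yy1-deleted libraries carried more of the genes of resting microglia. Markers of monocytes (median -0.83) and border-associated macrophages (-0.82) were called lower by camera in the same libraries, with the preset correlation only. Bulk values do not separate a change within microglia from a change in the share of such cells. P2ry12 (chromosome 3, 59216272 to 59262871) rose from 1659 ± 149 to 3847 ± 305 CPM, a log2 fold change of 1.21 (SE 0.10, adjusted p = 6.3e-06). Olfml3, which encodes a secreted matrix protein, rose from 411 ± 109 to 1561 ± 59.4 CPM (log2 1.92, adjusted p = 4.7e-06), and Slc2a5 from 33.4 ± 4.07 to 217 ± 30.9 CPM (2.70, adjusted p = 2.5e-06). Tmem119 (log2 0.95) and the Fc receptor-like gene Fcrls (1.49) rose too, with adjusted p of 4.9e-04 and 2.0e-04. Each of these 5 genes was called in all 13 alternatives. Cx3cr1 rose by 0.50 (adjusted p = 0.0386) but was called in 6 of 13 alternatives, and its adjusted p ran from 9.7e-04 to 0.211. It lost its call with scaling by total counts and with any 1 of the 6 libraries left out, as with 0.136 without control replicate 1. Cx3cr1 is also the locus of the Cre driver, so its counts may not be comparable between these genotypes. Gpr165 rose by 2.56 (adjusted p = 0.00385, 0.0686 without control replicate 1).

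Spp1, Gpnmb, Apoe and Msr1, each higher in the wild-type day 6 library than in sham, fell, while the disease-associated microglia list had 4 genes called higher and 4 lower. Spp1 fell by 1.73 on the log2 scale (SE 0.17), from 1442 ± 359 to 435 ± 65.1 CPM, with an adjusted p of 2.1e-05. Gpnmb fell by 1.43, from 314 ± 18.4 to 117 ± 20.1 CPM (adjusted p = 1.6e-04), and Apoe by 0.71, from 3416 ± 140.3 to 2085 ± 257 CPM (adjusted p = 0.00114). The lipid uptake genes Cd36 (log2 -3.69, adjusted p = 1.5e-04) and Msr1 (-2.27, adjusted p = 4.9e-04) fell, as did Plin2 (-0.92, adjusted p = 0.0164), whose call was lost without control replicate 1 (0.0628), 2 (0.126) or 3 (0.0625). Igf1 was lower at 85.5 ± 30.4 against 152 ± 25.8 CPM (log2 -0.84, SE 0.25) in 3 of 3 libraries, and did not pass the threshold (adjusted p = 0.0923). It was called in 4 of 13 alternatives, with adjusted p from 0.00260 to 0.325. Lpl did not pass either (-0.49, adjusted p = 0.235), and Clec7a, a lectin receptor gene also linked to disease-associated microglia, rose by 1.41 (adjusted p = 0.00124).

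Several other genes were near 0 CPM in Yy1-deleted libraries. These libraries had counts in 12222 to 13041 genes, against 13865 to 14554 in controls. Hif3a and Zbtb16 were also lower in the wild-type day 6 library than in floxed controls, in tables normalized separately. Hif3a, a hypoxia-inducible factor gene, stood at 82.2, 34.2 and 28.3 CPM in controls and at 0 counts in all 3 Yy1-deleted libraries (adjusted p = 8.6e-06, 0.00254 without control replicate 1). The smooth muscle myosin gene Myh11 was at least 140-fold lower (adjusted p = 0.00188), and the kinase gene Map3k6 fell from 56.0 ± 26.0 to 0.131 ± 0.227 CPM (log2 -8.70, adjusted p = 8.6e-06). The zinc finger gene Zbtb16 fell from 93.3 ± 47.5 to 1.05 ± 1.57 CPM, with 2.86, 0 and 0.296 CPM in the Yy1-deleted libraries (log2 -6.51, adjusted p = 1.8e-04, 0.0510 with limma-voom, range 2.7e-51 to 0.0510). Klf9 fell from 61.6 ± 13.2 to 1.73 ± 1.86 CPM, with 1.48, 3.70 and 0 CPM in the Yy1-deleted libraries (-5.11, adjusted p = 7.8e-04). The coagulation factor gene F13a1 (-2.16, adjusted p = 0.00296) fell as well. Fkbp5, a steroid receptor co-chaperone gene named after its values were seen, fell from 277 ± 64.2 to 45.4 ± 2.35 CPM (-2.61, adjusted p = 2.5e-06).

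Single genes of heat shock and glycolysis rose. Of 21 measured genes in the glycolysis and hypoxia list, 3 were called higher and 0 lower (camera adjusted p = 0.104 with an estimated correlation). Of 21 in the dissociation and immediate early list, 4 were called higher and 1 lower (0.411 with an estimated correlation). The heat shock gene Hspa1b rose from 108 ± 44.8 to 464 ± 169 CPM (log2 2.10, adjusted p = 4.9e-04), Hsph1 by 1.97 (0.00485, 0.0851 without control replicate 1) and the immediate early gene Nr4a1 by 2.14 (adjusted p = 0.00513, 0.0936 without control replicate 1). The hexokinase gene Hk2 rose by 0.88 (adjusted p = 0.00256) and the collagen hydroxylase gene P4ha1 by 1.27 (adjusted p = 7.8e-04). The integrin gene Itgam rose by 0.85 (adjusted p = 4.9e-04), and the transcription factor gene Irf8 by 0.66 (adjusted p = 0.0123), with 0.0628, 0.0742 and 0.0514 without control replicate 1, 2 and 3. Il1b, at 46.4 ± 39.1 against 9.32 ± 5.92 CPM, did not pass (adjusted p = 0.0981) and its groups overlapped.

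In all, edgeR called 192 genes higher and 130 lower of 12387 tested, with 1748 at an unadjusted p under 0.05. The groups did not overlap in 2610 genes, where chance gives 10% of genes, and in all 322 called genes. Of the calls 59.6% were higher, and with scaling by total counts, which shifts all log2 fold changes by -0.105, 127 were higher and 193 lower (39.7% higher). Without control replicate 1 the calls were 58 higher and 39 lower, and without control replicate 2 they were 98 and 67. Without control replicate 3, 78 were lower. A permutation of 3 against 3 libraries cannot give a p under 0.1. Log2 CPM correlated across genes at 0.907 to 0.921 between controls and 0.802 to 0.835 between Yy1-deleted libraries, and the biological coefficient of variation was 0.576.

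Of the 26 lists tested with camera, 12 were called, and 1 of them, homeostatic microglia, with an estimated correlation as well. In that list 17 of 23 genes were called higher, 20 adjusted over the list alone, and the median log2 fold change was 0.96 (adjusted p = 3.1e-37, 0.0402 with an estimated correlation). Glycolysis and hypoxia had a median of 0.33 (adjusted p = 6.6e-05, 0.104 with an estimated correlation), and lysosome 0.26 (adjusted p = 2.3e-04, 0.217 with an estimated correlation). The dissociation and immediate early genes had a median of 0.34 (adjusted p = 6.6e-05, 0.411 with an estimated correlation), and cytosolic ribosomal proteins 0.14 (adjusted p = 0.00109, 0.2797 with an estimated correlation). Interferon response (0.32, adjusted p = 0.00160), antigen presentation (0.31, 0.00301) and microglial transcription factors (0.12, 0.00339) were called higher, with adjusted p of 0.217, 0.193 and 0.247 with an estimated correlation.

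Lipid uptake and efflux was called lower (median -0.14, adjusted p = 0.0257), with 4 genes called lower and 0 higher, 5 and 2 adjusted over the list alone. Its adjusted p was 0.217 with an estimated correlation, 0.0917 without control replicate 3 and 0.0716 without Yy1-deleted replicate 1. Markers of monocytes (median -0.83, adjusted p = 0.00336) and border-associated macrophages (-0.82, 0.00763) were called lower, with 0.2797 and 0.291 with an estimated correlation. Endothelial and mural markers were called lower at a median of -0.48 (adjusted p = 0.0257, 0.437 with an estimated correlation, 0.156 without control replicate 3 and 0.0989 without Yy1-deleted replicate 3). Disease-associated microglia had 4 genes called higher and 4 lower, 8 and 8 adjusted over the list alone, with a median of 0.15, a mean of -0.10 and an upward test (adjusted p = 0.645). Median and mean also differed in sign for growth factors (0.21 and -0.19), phagocytic receptors (0.24 and -0.17) and cytokines (-0.03 and 0.29), none of them called. Cell cycle (adjusted p = 0.669), oxidative phosphorylation (0.669) and YY1 partners in chromatin looping (0.669) were not called.

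Of 411 measured genes that were higher on day 6 after stroke than in sham, 31 were called lower and 1 higher in Yy1-deleted libraries. The list had a median of -0.61 (adjusted p = 1.0e-12, 0.154 with an estimated correlation). Without 26 markers of other cell types, 13 of them endothelial or mural, the camera adjusted p was 1.2e-12. The removal of markers was chosen after the data were seen. Only genes of the fixed marker lists were taken out, so other genes of those cells could remain. The result therefore does not tell a change within microglia from a change in the cells present. The 57 genes higher in EGFP-positive cells on both days had a median of -0.20, with 6 called lower and 1 higher (adjusted p = 0.0302, 0.247 with an estimated correlation). That call was lost without control replicate 3 (0.388), Yy1-deleted replicate 1 (0.0689) and Yy1-deleted replicate 3 (0.0838), and it kept an adjusted p of 0.0244 without 2 markers of other cells. The other 4 derived lists were not called, with adjusted p from 0.329 to 0.934.

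**Figure D4:**
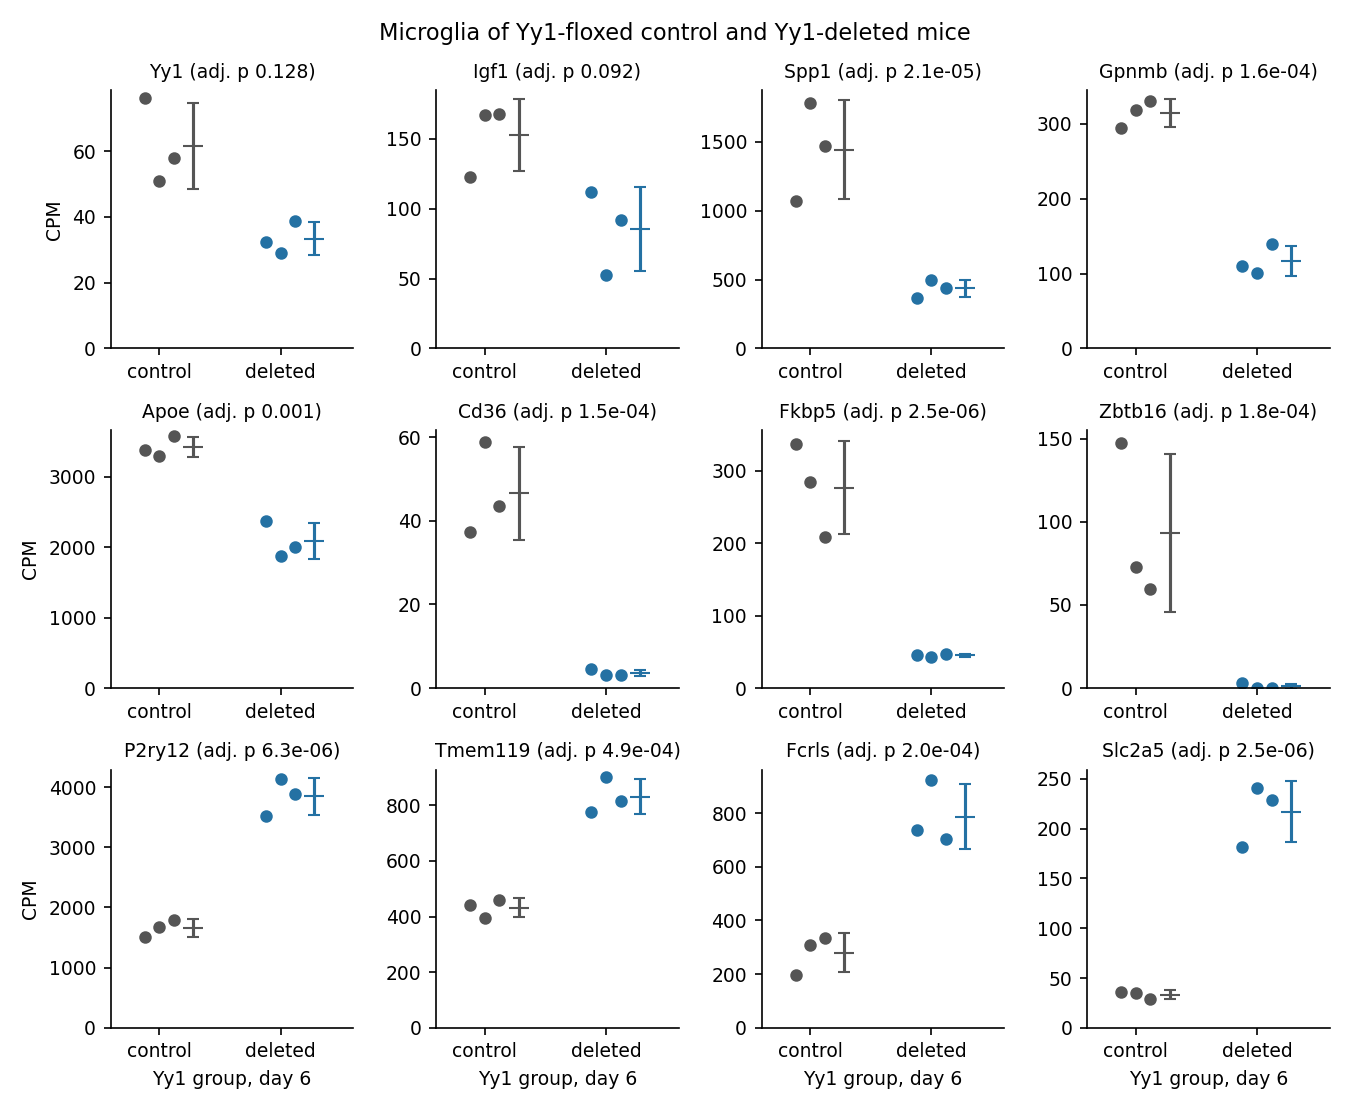
Expression (CPM) of 12 genes in each of 3 floxed control and 3 Yy1-deleted day 6 libraries, with the mean and SD of each group. P2ry12, Tmem119, Fcrls and Slc2a5 were higher in every Yy1-deleted library, and Yy1, Igf1, Spp1, Gpnmb, Apoe, Cd36, Fkbp5 and Zbtb16 were lower in every one.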

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

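The comparison of list medians between the days was planned, and the tests of explanations below were chosen only after the results were seen. In 5 gene lists the EGFP difference pointed one way on day 6 and the other way on day 14, and every one of the 10 medians lay outside the central range of its random lists. Interferon response genes had a median log2 ratio of EGFP-positive to EGFP-negative cells of -1.09 on day 6 and 0.91 on day 14. Antigen presentation genes had medians of -1.33 and 0.32, and cytosolic ribosomal proteins -0.57 and 0.44. Markers of monocytes had medians of -2.71 and 3.502, and markers of neutrophils -6.42 and 6.51. The differences between the days were not tested, since each state had 1 library per day, and the days also differ in table and sequencer.

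Neutrophil genes in the EGFP-negative day 6 library may explain the day 6 side of the neutrophil median. That library stood above the wild-type day 6 library in 10 of 11 measured neutrophil genes, with a median log2 ratio of 5.17, and held S100a8 at 3106 CPM, S100a9 at 4937 CPM and Ngp at 1724 CPM, against 73.0, 136 and 115 CPM. Neutrophils are a candidate source, although a gate on intermediate CD45 and CD11b would remove most of them. A swap of the EGFP labels on one day is argued against by Igf1, whose smaller log2 ratio over both days was 1.51 in favor of EGFP-positive cells. The day 14 side, with Ngp at 527 CPM in EGFP-positive cells, was not tested, and a change of the microglia themselves remains open.

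Both day 14 EGFP libraries stood apart from the other 13. Their Spearman rho was 0.864 with each other and at most 0.492 with any other library, against at least 0.536 among the others, over 6968 genes. RNAs without a poly(A) tail had a median log2 ratio of -3.93 to the other libraries, with 23 of 25 more than 2 log2 units below them, which is consistent with a library preparation that leaves them out. Depth alone is argued against, because the wild-type day 14 library, with fewer counts in total, had a median of -0.28. The 4 Y-linked genes had 0 counts in both and Xist stood at 76.0 and 82.8 CPM, which is consistent with cells from female mice, although the protocols name male mice, and the parts of library, sex, sequencer and day cannot be told apart.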

How the results depend on the processing

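The minimum of 10 counts in both libraries and the removal of marker genes from the derived lists were chosen after the data were seen. The other alternatives were planned. For the Yy1 genes named, 692 results kept direction and side of the threshold, 106 lost their call, 7 gained one and 0 reversed. Of 56 named genes called, 27 were called in all 13 alternatives and 46 in all that kept the 6 libraries. The called genes numbered 127 higher with total counts, 380 higher and 366 lower with DESeq2, 289 higher with limma-voom, and 309 higher and 266 lower without a filter. With 1 library left out they ran from 58 to 166 higher and from 39 to 151 lower. With the replicate number as a block, 219 were higher and 194 lower, 313 of them shared with the fit without it.

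With an estimated correlation camera called 1 of the 12 lists and 0 of the 2 derived lists. With 1 library left out 1 to 2 derived lists were called. Directions reversed only in lists that were not called: cytokines and chemokines with genes of at least 5 CPM (adjusted p = 0.889), and with 1 library left out growth factors (0.312 to 0.923), cell cycle (0.389 to 0.970), mitochondrial ribosome (0.671 to 0.936), dendritic cells (0.679 to 0.941), astrocytes (0.447 to 0.921), genes higher on day 6 than day 1 (0.230 to 0.876) and genes lower in EGFP-positive cells (0.338 to 0.960). The cause was not tested.

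The number of genes past a size rule moved with the CPM minimum by construction. At 5 CPM the higher genes were 750 on day 1, 895 on day 6 and 1635 on day 14 against sham, and 981 and 1612 between EGFP states on days 6 and 14. The lower genes were 1485 on day 14 and 2970 on day 28 against sham, 3623 on day 28 against day 6, and 1575 and 1285 between EGFP states. At 50 CPM the higher genes were 203, 215, 550 and 465 from day 1 to day 28 against sham, 374 on day 28 against day 6, and 325 and 327 between EGFP states. The lower genes were 183 on day 14, 352 on day 28, 435 on day 28 against day 6, and 486 and 338 between EGFP states, and 22 were higher and 24 lower on both days.

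A pseudocount of 5 CPM left 95 genes lower on day 1 and 3 on day 6. With at least 10 counts in both libraries 628 genes were lower on day 28 than in sham and 649 lower than on day 6. That minimum leaves out by construction the genes with the fewest counts on day 28, so it does not show whether they fell. DESeq2 called 18 genes higher and 13 lower in the EGFP fit. Of the list medians, 10 of 450 in the time course and 4 of 159 between EGFP states moved out of their interval. Ratios of named genes moved more often. In the time course 487 results moved by more than the counting interval and 668 did not, with 324 of the moves at a pseudocount of 5 CPM. Between EGFP states 87 moved and 129 did not. Depth limits genes under 3 counts. If the even counts in the whole-count tables arose by counting both mates of a fragment, the counting intervals are too narrow.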

Other observations

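The splits of the Yy1 libraries were planned, and the other tests in this part were chosen only after the results were seen. Slc2a5, Gpr165 and Olfml3 had log2 ratios of -4.10, -4.14 and -2.32 on day 1 against sham in wild-type cells and were higher in Yy1-deleted libraries on day 6. On day 6 against sham their ratios were -1.97, -3.42 and -0.62, of which only that of Gpr165, an orphan receptor gene, passed the size rule. With the deletion they rose by 2.70, 2.56 and 1.92, and the call of Gpr165 was lost without control replicate 1 (adjusted p = 0.0686). These values come from tables normalized separately.

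Of the 10 splits of the 6 Yy1 libraries into 3 and 3, 1 split, the real one, gave as many genes higher (192, highest other 0), and 1 gave as many genes lower (130, highest other 0). For gene lists 1 split gave as many as the real 12 (highest other 5), and for derived lists 3 splits gave as many as the real 2 (highest other 3). The 10 splits are too few for a share under 0.05.

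In Yy1-deleted libraries 7 genes that respond to steroid and stress signals were far lower: Hif3a, Map3k6, Zbtb16, Klf9, Pik3ip1, Fkbp5 and Ddit4, with a median log2 fold change of -5.11, though Ddit4 (adjusted p = 0.0373) lost its call without control replicate 1 (0.361), 2 (0.0879) or 3 (0.0848) or Yy1-deleted replicate 3 (0.0644). In all, 47 of 6717 genes lay more than 1 log2 unit below the lowest control in all 3 deleted libraries, against 1.42 expected. This argues against loss at random and independent in each library, for these genes as a set. The 7 are among them but were picked for being lower. In the other direction there were 22 genes against 0.044 expected. Deleted libraries had counts in 12222 to 13041 genes and controls in 13865 to 14554, and a loss shared by the deleted libraries was not tested. Endothelial transcripts were lower, with a median of -0.35 over 9 genes, the most abundant being Vwf at 244 and 156 CPM. The 95% interval of -0.83 to -0.11 treats these genes as independent. A somewhat smaller share of endothelial cells is therefore possible. A fall of that size is argued against as the source of the median of -5.11. Fewer mural cells remain open, since the only measured member of that list, Acta2, had a log2 fold change of -1.09 (SE 1.26). Outside that list, Myh11 and Mylk were at 0 counts in Yy1-deleted libraries. Tagln, named after its values were seen, had a log2 fold change of -4.67 (edgeR adjusted p = 0.129). The CD45 and CD11b gate should leave out vascular cells, but vascular transcripts such as Vwf were present. Less glucocorticoid receptor activity, which may depend on Cre or on the deletion, also remains open. Of 25 known target genes, 23 were measured, with a median log2 fold change of -0.79. That median includes the 7 genes picked for being lower, and it was -0.10 without them. Of the 23, the 7 picked genes were the only ones called lower. Sgk1 was the only one called higher (0.72, edgeR adjusted p = 0.00162). The others were lower or higher without a call.

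In the day 14 EGFP libraries Yy1 stood at 1.41 and 1.71 CPM, against 49.0 CPM or more in the wild-type libraries, and Actb at 449 and 399 CPM, against 3800 CPM or more. Hif3a stood at 6.79 CPM in the wild-type day 6 library and Zbtb16 at 13.6 CPM, against 48.2 and 93.3 CPM in floxed controls, in tables normalized separately.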
